A study of Arabidopsis thaliana with 6 samples.

How the data were processed

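RNA of leaves of 3-week-old Arabidopsis thaliana plants of the accession Col-0, a standard wild type of plant genetics, was separated by the submitters into a nuclear and a cytoplasmic fraction. There were 3 samples of each fraction, numbered 1 to 3. Per the labels' protocols, total RNA of each fraction was purified with TRI Reagent, amplified as antisense RNA with the MessageAmp II kit, reverse transcribed and labelled with Cy3 or Cy5, and samples of both dyes were co-hybridized. In each group 2 samples were labelled with Cy3 and 1, replicate 2, with Cy5. The array type named in the labelling protocol does not match the number of spots in the scanner files, and the scanner files were followed. The tissue tag of cytoplasm replicate 3 reads flower whereas its source name reads leaf. That sample was kept in the cytoplasm group, and the counts of called probes, the class shifts and the shares per sample were also compared without it.

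Each sample came with the scanner output of 1 array, extracted with Feature Extraction 11.5.1.1 per the file headers. The deposited spot intensity values are median pixel intensities of each spot and of its local background in 2 channels, neither background-corrected nor normalized. The deposited processed intensity was background-subtracted, spatially detrended and dye-normalized by the scanner software per the file headers. The authors' deposited value table holds log2 values, and limma is named without a version in the submitters' processing notes. Setting each table column against the scanner values showed that for nucleus replicates 1, 2 and 3 and cytoplasm replicate 1 the table is the log2 intensity of the labelled channel after loess normalization between both channels, with no background correction. Column medians were 9.51, 8.09, 7.84 and 8.95 for these 4 samples and 9.00 and 9.00 for cytoplasm replicates 2 and 3. For the last 2 samples the table and the scanner files disagree, and the scanner files were used as assigned to the samples. The column of cytoplasm replicate 2 was met by the same steps from the Cy5 channel of the file of cytoplasm replicate 3. Direction and scale of the table are therefore known for 5 columns, and which array lies behind the column of cytoplasm replicate 3 stays unknown.

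Every array held 180880 spots, of which 176026 carried probes and 4854 controls. Of 155747 distinct probes, 20279 were printed in 2 spots. The probes are numbered, and 76901 of them carry the suffix _r and share their number with a probe without it. The meaning of the suffix and of the numbers is not given in the sources used here. Neither the files nor the reference table used here pair these probes with genes, so that the probe was the unit of every test, and the 19 gene lists fixed in advance, the cell type and flower markers, gene structure and intronic probes were not analysed here. In place of annotated transcript classes, probes were divided by number alone, a division made after seeing the probe names. Probes up to number 32000 are called early-numbered, those from 32001 to 35000 middle-numbered and those from 35001 on late-numbered, because probes without an _r partner are concentrated in the middle range. These 3 ranges hold 63999, 4110 and 87638 probes.

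The value of a sample was the channel of its labelled dye. What the other channel of each file holds is not stated in the labels, and it entered no value of the main settings. It enters the alternatives with loess, the processed intensity, the series table and cytoplasm replicate 2 read from another file. Spot medians were corrected for the local background with normexp (limma 3.58.1 in R 4.3.3) with an offset of 50. The planned mean spot signal was replaced by the median, which the scanner files give. Log2 values were quantile normalized over the 6 channels, spots with an outlier mark were left out, and the spots of a probe were averaged. Probes well above background by the scanner software's mark in at least 3 of the 6 channels, 43066 in number, were tested with lmFit and eBayes with a trend, with dye as covariate, and p-values were adjusted after Benjamini-Hochberg at 0.05. Shifts of probe classes were tested with limma's camera with a preset correlation of 0.01, and again with an estimated one. With the preset, camera takes its degrees of freedom from the number of probes, and with an estimate from the arrays. Its p-values with the preset therefore treat probes much like replicates. Single values per sample were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 samples against 3. The number of arrays limits the precision of every value. Nothing in the labels says that replicates came from separate plants. The p-values of single probes therefore measure the spread between these samples, which may be technical.

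The rule for named probes, fixed before the data were examined, took those past the threshold with the largest differences whose 3 samples of one group all lay above those of the other and which were well above background in the higher group. Where none passed, those with the smallest unadjusted p were taken and given as not passing, here among probes that met the other conditions. The rule allowed more probes, and 8 met it in the higher direction. With no gene names, 2 probes are named per direction, a cut that was not part of the rule. A fold against a group in which a probe was not well above background on any array is given as a lower bound: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

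The fit was tested on simulated data with the real probes' means and spreads, in which 200 of 42958 probes were changed on 6 arrays. The mean of the estimated changes was 3.84 for a true log2 change of 4, and 4% of those probes were recovered, with 0 unchanged probes called. With 5 arrays, without nucleus replicate 1, 15% of probes changed by a log2 of 4 were recovered among 43061, and 0 unchanged ones were called. In both designs 0 of 200 probes changed by a log2 of 2 were recovered. Far fewer probes were changed than the 8110 called in the real 5-array fit, and the simulated noise was independent between probes. These shares therefore do not give the power or the error rate of the real fits. The camera test called a simulated log2 shift of 0.5 in 14319 probes with the preset and the estimated correlation, and made no call without a shift. The class was drawn at random from probes with independent noise. How the test behaves when the probes of a class correlate was therefore not covered.

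Alternatives fixed in advance were no background correction, an offset of 16, the processed intensity, scaling to the 75th percentile, loess with Aquantile normalization, the series table, no filter and a filter on all 6 channels, no dye term, the replicate number, slide and scan day as blocks, no trend, and leaving out each sample. Slides and scan days were taken from the file headers. The 6 arrays lay on 4 slides, each with samples of 1 group, and were scanned on 3 days. The first scan day held replicate 1 of both groups, the second nucleus replicates 2 and 3 and the third cytoplasm replicates 2 and 3. The repeat of all counts without nucleus replicate 1, the central part of the array, the reading of cytoplasm replicate 2 from another file and the shares among the brightest probes were chosen after seeing the data.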

Results

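The nuclear and cytoplasmic RNA of Arabidopsis leaves was set side by side to ask which transcripts are relatively more abundant in which fraction. The 3 nuclear and 3 cytoplasmic samples were measured on 155747 probes each. Nuclear samples lit up far more of the array than cytoplasmic ones. A share of 42.9%, 51.8% and 66.5% of probes was well above background in nucleus replicates 1, 2 and 3, against 13.3%, 5.16% and 9.31% in cytoplasm replicates 1, 2 and 3. The mean was 53.7% ± 11.9 (SD, n = 3) in nuclear RNA and 9.25% ± 4.06 (SD, n = 3) in cytoplasmic RNA, with every nuclear sample above every cytoplasmic one (exact two-sided permutation p = 0.1, the smallest possible). The median local background was higher around the spots of the cytoplasm arrays, at 285.5, 848.5 and 271.0 against 159.0, 257.0 and 102.0, and their bright-corner control spots, net of background, were dimmer, at 6900 ± 2480 (SD, n = 3) against 20600 ± 3860 (SD, n = 3). The gap in detection thus went along with a gap in array brightness. The measured cytoplasmic signal was also concentrated in fewer spots. The brightest 1% of probe spots carried 64.0%, 55.6% and 63.2% of the net signal of cytoplasm replicates 1, 2 and 3, and 11.1%, 42.7% and 41.9% of that of nucleus replicates 1, 2 and 3 (exact two-sided permutation p = 0.1). Saturation clips the brightest spots and can lower their share. Saturated probes numbered 123, 613 and 651 in the nuclear samples and 96, 52 and 73 in the cytoplasmic ones, in the same order. The low share of nucleus replicate 1 belongs to an array with bright outer spots.

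**Figure D1:**
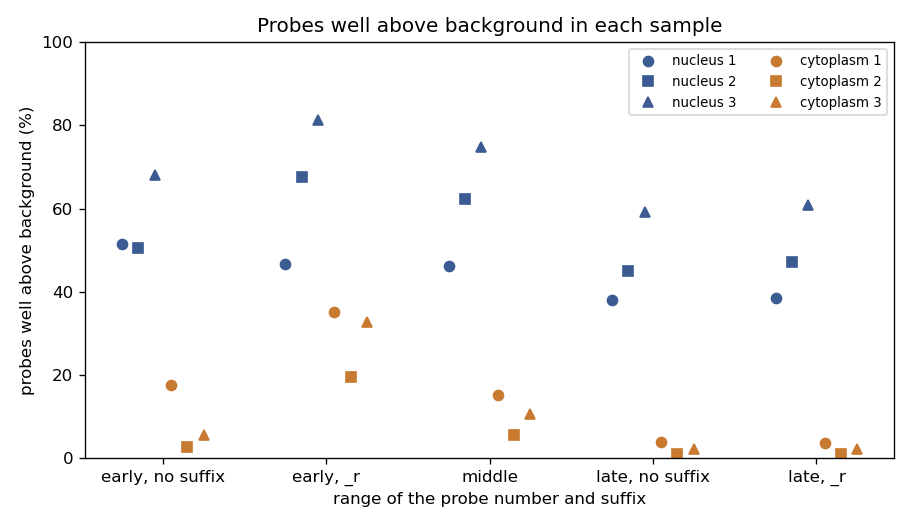
Share of probes well above background (%) in each of the 6 samples, by range of the probe number and suffix. Each point is 1 sample, blue for nucleus and orange for cytoplasm. Late-numbered probes lie between 37.9% and 61.0% in nuclear samples and between 0.876% and 3.77% in cytoplasmic ones.

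The gap in detection ran through every class of probes and was as a ratio, widest for late-numbered probes. These were well above background in 48.1% ± 11.1 (SD, n = 3) of cases in nuclear samples and 2.24% ± 1.4 (SD, n = 3) in cytoplasmic ones, while early-numbered probes reached 61.0% ± 12.9 and 18.8% ± 7.68 (SD, n = 3 each). Among early-numbered probes, those with the _r suffix were detected more often than those without it in cytoplasmic samples, at 29.1% ± 8.50 against 8.47% ± 7.90 (SD, n = 3 each). A set of 22101 probes was well above background on all 3 nucleus arrays and on no cytoplasm array, and 60.4% of it was late-numbered, against 56.3% of the array. The reverse held for 1 probe. Without nucleus replicate 1 these counts were 57948, of which 61.6% were late-numbered, and 2. On all 6 arrays 6578 probes were well above background, of which 8.50% were late-numbered.

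Nucleus replicate 1 stood apart from the other samples. Over the 43066 probes tested, its log2 values correlated at r = 0.196 and 0.184 with nucleus replicates 2 and 3 and at 0.0607 to 0.153 with the cytoplasmic samples. Nucleus replicates 2 and 3 correlated at 0.969 with each other, the cytoplasmic samples at 0.807 to 0.872 among themselves, and these 5 samples at 0.673 to 0.747 between the groups. These correlations are across probes, which are not independent replicates. Spots of the same probe on the array of nucleus replicate 1 correlated at 0.223, against 0.868 to 0.971 on the other arrays. The median signal of this array was 303 in its central part and 1379 outside it, against 192 and 174 on the array of nucleus replicate 3. Counts of called probes are therefore given on 6 arrays, as planned, and on 5 arrays without nucleus replicate 1, a repeat chosen after seeing the data.

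**Figure D2:**
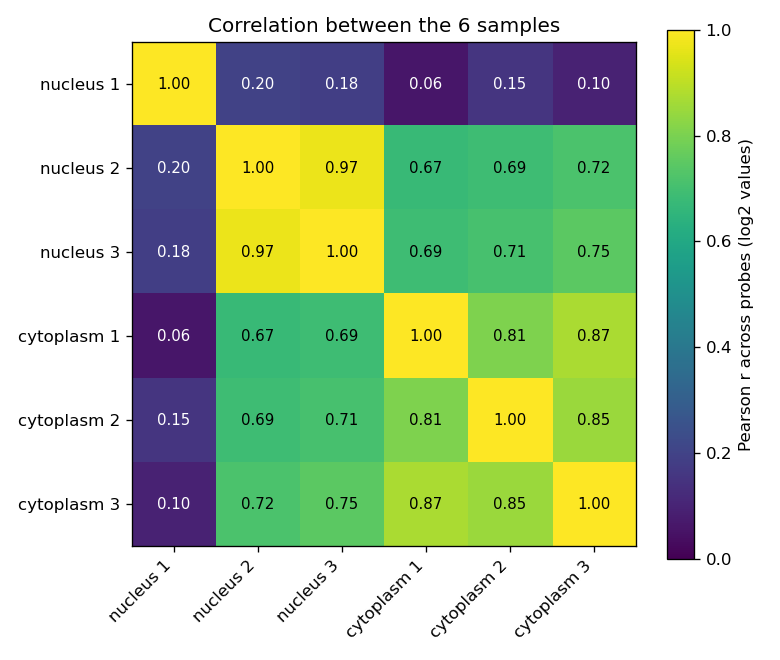
Pearson correlation of log2 values across the 43066 tested probes for each pair of the 6 samples. Nucleus replicate 1 correlates with the other 5 samples at 0.0607 to 0.196, and all other pairs lie between 0.673 and 0.969.

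**Figure D3:**
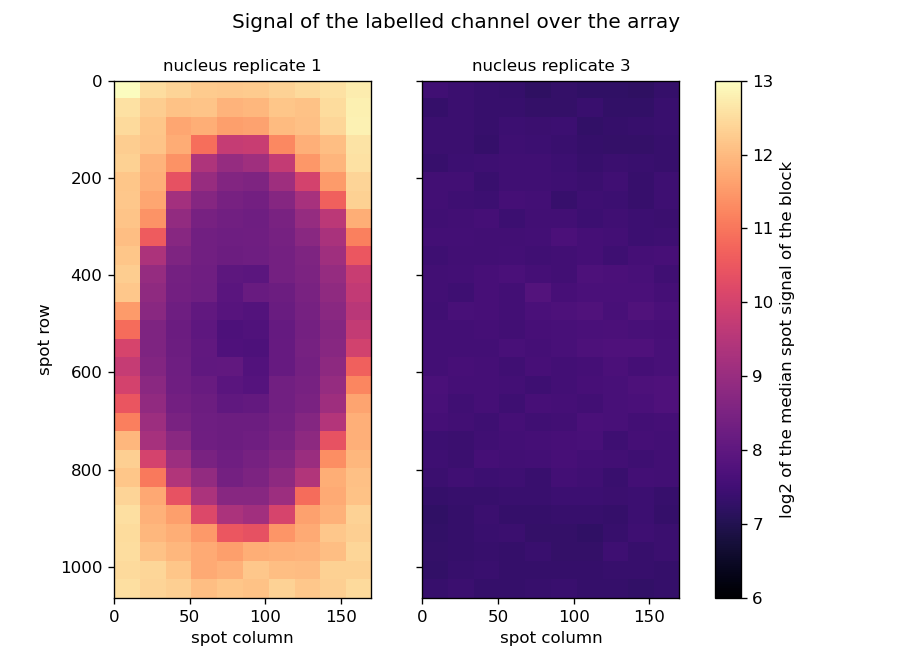
Signal of the labelled channel over the arrays of nucleus replicates 1 and 3, as log2 of the median spot signal in blocks of spots, against spot row and column. On nucleus replicate 1 the outer spots are brighter than the central ones, with medians of 1379 and 303. On nucleus replicate 3 both parts lie close together, at 174 and 192.

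The 5-array test kept the 43066 probes of the filter over 6 channels, which counts the marks of nucleus replicate 1. On 5 arrays, 5169 of 43066 probes were higher and 2941 were lower in nuclear than in cytoplasmic RNA (limma, adjusted p under 0.05). Of these, 4915 and 2852 differed at least 2-fold. Late-numbered probes made up most of the first set, with 3730 of 16519 higher and 360 lower. Early-numbered probes went the other way, with 1284 of 25155 higher and 2502 lower, and those with the _r suffix alone gave 1074 higher and 1994 lower of 14759. The planned test on all 6 arrays called 8 probes higher and 0 lower, and 6721 and 2196 passed an unadjusted p of 0.05. All 8 were also called higher on 5 arrays. The counts on 6 arrays moved with each sample left out. They were 5169 higher and 2941 lower without nucleus replicate 1, 76 and 17 without nucleus replicate 2, 2650 and 1213 without nucleus replicate 3, 0 and 0 without cytoplasm replicate 1, 0 and 0 without cytoplasm replicate 2, and 31 and 0 without cytoplasm replicate 3. Without cytoplasm replicate 1, 5328 higher and 578 lower probes passed the unadjusted threshold, and 4991 and 1547 did without cytoplasm replicate 2.

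The balance of the 5-array calls depended on which probes were tested. Of the calls, 63.7% were higher in nuclear RNA. Among the 7849 probes well above background on all 5 arrays, 592 were higher and 2636 were lower, so that 18.3% of calls were higher. In that set late-numbered probes were also lower more often than higher, with 99 higher and 233 lower of 711, and early-numbered ones made up 476 of the 592 higher and 2333 of the 2636 lower. Among the 20685 probes well above background on at least 3 of the 5, 1403 were higher and 2862 lower. The wider set takes in many probes that only the brighter nucleus arrays measured: 3723 of the 5169 higher probes were not well above background on any cytoplasm array, whereas 8 of the 2941 lower ones were not well above background on either nucleus array. The narrowest set leans the other way, since it was limited by what the dimmer cytoplasm arrays measured. Just 2 probes were well above background on all 3 cytoplasm arrays and on neither nucleus replicate 2 nor 3. Neither balance is therefore free of the filter. Scaling to the 75th percentile in place of quantile normalization moved the median difference of all tested probes from 0.20 to 0.47 and gave 15459 higher and 3150 lower, or 83.1% higher. Leaving out nucleus replicate 2 gave 2467 higher and 1454 lower, leaving out nucleus replicate 3 2094 and 927, and leaving out cytoplasm replicate 2 1907 and 1045. Without cytoplasm replicates 1 or 3 the counts stayed within 1.5 times, at 7325 and 3966 and at 5667 and 2658.

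Slides held samples of 1 group each. With slide as a random block, which gave a correlation of 0.87 between arrays of a slide, 0 probes were called on 6 arrays by limma, with 1880 higher and 1392 lower at the unadjusted threshold. Replicate 1 of each group lay alone on its slide. The correlation therefore also takes in how far nucleus replicate 1 stood from nucleus replicates 2 and 3, and this fit cannot tell a slide effect from that array. On 5 arrays, where the nuclear samples share 1 slide, that block could be fitted without the dye term only and gave 6678 higher and 3674 lower. Its correlation was estimated at -0.19, which makes the test more liberal, so that this fit sets no limit on an effect of the slide. Scan day 1 held replicate 1 of both groups. With scan day and dye as blocks the comparison rests on these 2 samples and 1 residual degree of freedom, and 7108 probes were higher and 12485 lower. The residual spread comes from the arrays of the other scan days alone, so that these counts do not test the difference between the 2 samples. On the array of nucleus replicate 1, spots of the same probe also disagreed. Within scan day 1 the median difference over the tested probes, nuclear minus cytoplasmic, was -0.26 on the log2 scale.

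The probe Catma_IRHS_34483, of the middle range, had a log2 value of 14.04 ± 0.25 (SD, n = 3) in nuclear and 6.74 ± 0.50 (SD, n = 3) in cytoplasmic RNA and was at least 96.8-fold higher in nuclear RNA (limma, adjusted p = 0.0411). The late-numbered probe Catma_IRHS_49555_r was at least 145-fold higher, at 14.73 ± 0.21 against 7.45 ± 0.28 (SD, n = 3 each; limma, adjusted p = 0.0411). These bounds belong to the main settings only. Over the other settings the log2 differences were 5.35 to 7.95 for the first probe and 5.92 to 7.77 for the second. Both were well above background on all 3 nucleus arrays and on none of the cytoplasm arrays, and the second was saturated on 2 of the nucleus arrays. Both calls were lost without cytoplasm replicate 1 (limma, adjusted p = 0.231 for each), without cytoplasm replicate 2 (limma, adjusted p = 0.222 and 0.178) and with slide as a random block (limma, adjusted p = 0.32 for each). Among probes lower in nuclear RNA none passed on 6 arrays. Among probes separated by group and well above background in all cytoplasmic samples, the smallest unadjusted p belonged to 2 early-numbered probes. Catma_IRHS_08889 had 10.03 ± 0.93 in nuclear and 15.33 ± 0.59 in cytoplasmic RNA (SD, n = 3 each), a log2 difference of -5.30 ± 0.86 (SE; limma, adjusted p = 0.0554). Catma_IRHS_31441_r had 11.10 ± 0.48 and 15.58 ± 0.24, a difference of -4.49 ± 0.73 (SE; limma, adjusted p = 0.0554). On the 5 arrays both passed, with differences of -5.40 ± 0.39 (SE; limma, adjusted p = 1.46e-05) and -4.76 ± 0.28 (SE; limma, adjusted p = 6.11e-06). Both were well above background on all 6 arrays, and Catma_IRHS_08889 was saturated on 1 cytoplasm array, so that 2 measured its level there. They passed as well without nucleus replicate 2 (limma, adjusted p = 0.0311 and 0.0416) and without nucleus replicate 3 (limma, adjusted p = 2.2e-07 and 1.19e-06). They did not pass without cytoplasm replicate 1 (limma, adjusted p = 0.231 for each), 2 (limma, adjusted p = 0.222 for each) or 3 (limma, adjusted p = 0.114 and 0.169), nor with slide as a random block (limma, adjusted p = 0.406 and 0.603). With the table as deposited the differences were -1.81 and -2.11.

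Among the tested probes, late-numbered ones as a class were shifted towards nuclear RNA, by an amount that depended on the filter. On 6 arrays their median log2 difference was 1.07, against -0.34 for the other tested probes (limma camera, adjusted p = 3.21e-30, and adjusted p = 0.00236 with an estimated correlation). The estimate, 0.00883, lay below the preset of 0.01. The weaker p-value therefore comes from the degrees of freedom and not from a larger correlation. The filter favoured this direction, since it takes in probes well above background on all 3 nucleus arrays and on no cytoplasm array. Such probes were 13343 of the 16519 late-numbered probes tested and 7994 of the 25155 early-numbered ones. These p-values therefore cannot separate a shift from the filter. Without nucleus replicate 1 the medians were 0.55 and -0.01, a gap of 0.56 (camera, adjusted p = 1.24e-14, and adjusted p = 0.0201 with an estimated correlation). With no filter the gap on 6 arrays was 0.23 (camera, adjusted p = 0.014). Among probes well above background on all 6 it was 0.30 (camera, adjusted p = 0.000384), with both medians below 0, at -0.95 for late-numbered and -1.25 for other probes. Restricting the test to probes well above background on all 5 arrays left a gap of 0.05 with an adjusted p of 0.136 in camera, over 710 late-numbered probes. That set was limited mainly by the dimmer cytoplasm arrays. Probes with the _r suffix were lower than the rest by 0.44 on 6 arrays (camera, adjusted p = 0.00764), and the call was lost with an estimated correlation (adjusted p = 0.485). It was also lost without nucleus replicate 1, at -0.03 (camera, adjusted p = 0.259), and without cytoplasm replicate 3, at -0.28 (camera, adjusted p = 0.209), and the direction turned with 75th percentile scaling, at 0.34 (camera, adjusted p = 0.00173), and among probes well above background on all 6 arrays, at 0.59 (camera, adjusted p = 0.00023), or on all 5, at 0.97 (camera, adjusted p = 0.015). Scaling to the 75th percentile gave a gap of 0.61 on 6 arrays (camera, adjusted p = 2.03e-13). Within scan day 1 the gap was 2.78, a value of 1 array per group that rests on nucleus replicate 1, whose spots of the same probe disagreed.

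**Figure D4:**
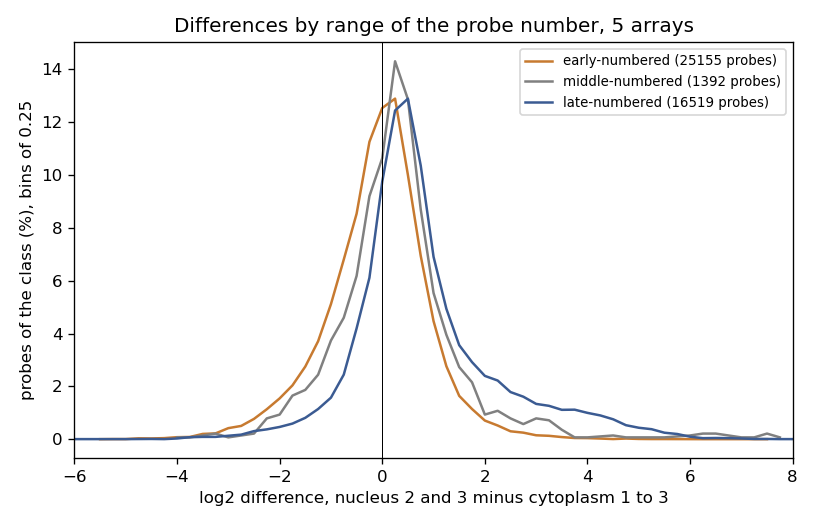
Distribution of the log2 difference between nuclear and cytoplasmic RNA on 5 arrays, in percent of the probes of each range of the probe number. The line of the late-numbered probes lies to the right of that of the early-numbered ones, with medians of 0.55 and -0.03.

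The same difference appeared in the ranking of probes within each array, which depends neither on scaling between arrays nor on the filter. Among the 8000 brightest probes of an array, 30.2% and 25.7% were late-numbered in nucleus replicates 2 and 3, against 9.50%, 10.4% and 8.41% in cytoplasm replicates 1, 2 and 3. Nucleus replicate 1 had 54.6%, close to the 56.3% of late-numbered probes on the array, a share that signal unrelated to the probe number would also give. The means were 36.8% ± 15.6 (SD, n = 3) and 9.44% ± 0.995 (SD, n = 3), with every nuclear sample above every cytoplasmic one (exact two-sided permutation p = 0.1). Nucleus replicates 2 and 3 alone had a mean of 27.9%, 18.5 points above the cytoplasmic mean. Among the 1000 brightest, the shares were 23.4% and 15.6% in nucleus replicates 2 and 3 and 8.40% to 9.20% in cytoplasmic RNA. Probes with the _r suffix filled 80.1% and 82.7% of the 8000 places in nucleus replicates 2 and 3 and 75.8% to 87.9% in the cytoplasmic samples, ranges that overlap.

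**Figure D5:**
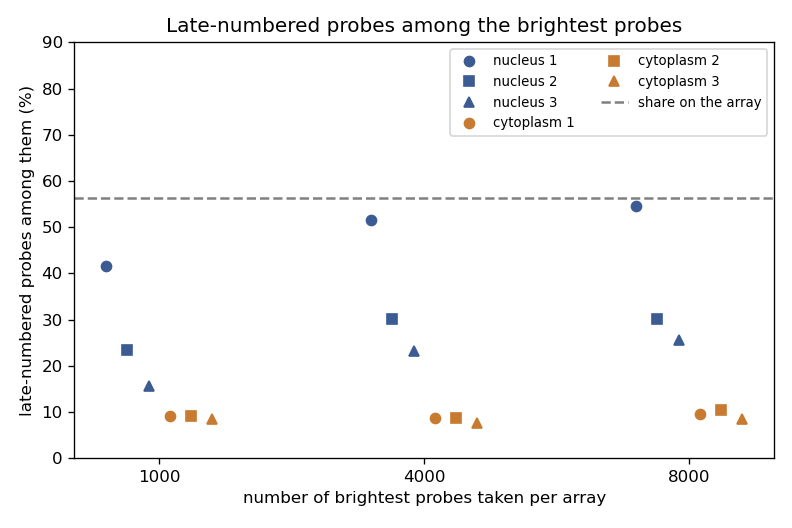
Share of late-numbered probes (%) among the 1000, 4000 or 8000 brightest probes of each array. Each point is 1 sample, blue for nucleus and orange for cytoplasm, and the dashed line is the share of such probes on the array, 56.3%. All nuclear samples lie above all cytoplasmic ones.

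Values of cytoplasm replicates 2 and 3 come with limits. The tissue tag of replicate 3 names flower while its source name is leaf, and no flower marker could be looked up. The authors' deposited log2 table agrees within 0.001 with the labelled channel of the scanner file for 100% of the 135468 probes printed once in the other 4 samples, and for 0.514% and 0.605% of them in cytoplasm replicates 2 and 3. Using that table with quantile normalization gave 0 higher and 0 lower probes on 6 arrays by limma, with 6347 and 2806 at the unadjusted threshold, and 5940 higher and 3237 lower on 5 arrays.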

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

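Tests on nucleus replicate 1, on the table, on DNA or labelling of both strands and on slides were chosen after related results were seen, while those on other splits were not. The test on dimmer arrays used a measure chosen after seeing the data, with its bound set before its value was computed. Signal was found in channels and spots that the main comparisons did not use. Of 53 positive control probes, 9 lay above the 99th percentile of the negative control spots on all 6 arrays. The channel of each file that the labels do not assign to the sample held probe spots well above background in 44.7%, 72.0% and 33.9% of cases for nucleus replicates 1, 2 and 3 and in 7.41%, 4.33% and 3.97% for cytoplasm replicates 1, 2 and 3. Its log2 signal correlated across probe spots with the labelled channel at 0.989, 0.952 and 0.906 on the nucleus arrays and at 0.889, 0.881 and 0.865 on the cytoplasm arrays.

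Nucleus replicate 1 was unlike every other sample. A misplaced spot grid is argued against: of 168 shifts of up to 6 rows or columns none gave a correlation with nucleus replicate 3 above -0.0396, while the unshifted grid gave 0.274. A mislabelled sample or a different RNA would by itself leave spots of the same probe in agreement, and they correlated at 0.223. A candidate explanation is signal towards the edges of the array that depends little on which probe a spot carries. The correlation of spots of the same probe was 0.804 in the central part and 0.350 outside it, a difference of 0.454. Not all kinds of spots were equally bright. Dark-corner and negative control spots of this array had medians of 364 and 297, against 742.5 for probe spots. The positions of the control spots were not compared. Signal that depends little on the probe would lower the agreement of spots for any RNA. Whether the RNA was also mislabelled or different therefore stays open. No biological explanation was tested for this array.

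The deposited table and the scanner files disagree for cytoplasm replicates 2 and 3. Another normalization of the table is argued against by the other 4 samples, whose values were met in 100% of single-spot probes by the same steps. An exchange of the 2 columns would make each column match the other replicate's labelled channel, and at most 0.614% of probes did. For cytoplasm replicate 2 the values may come from another array than its own file, since the Cy5 channel of the file of cytoplasm replicate 3 met 100% of them. For cytoplasm replicate 3 this stays open, since no same-dye channel of another file met more than 0.554%. No biological explanation applies to a disagreement of files.

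Among tested and among the brightest probes, late-numbered ones were relatively more abundant in nuclear RNA, though hardly so among probes above background on all 5 arrays. Dimmer cytoplasm arrays are argued against for the brightest probes, where the lower of nucleus replicates 2 and 3 lay 15.3 percentage points above the highest cytoplasm array, against a range of at most 4.55 within these groups. That margin was smaller among the 1000 brightest, 6.4 against a range of 7.8. DNA or labelling of both strands in the nuclear samples stays open: early-numbered probes without suffix took no larger share of the brightest probes that were not late-numbered, with a difference of -1.16 points between the nearest nuclear and cytoplasm arrays, but the range within the cytoplasm arrays was 12.8. The wide detection at low signal does not settle it either, since early-numbered probes without suffix were well above background more often than late-numbered ones on nucleus replicates 2 and 3, by at least 5.58 points, and also on every cytoplasm array, by 1.63 to 13.7 points. These comparisons read the suffix as a strand, which the sources do not state. Late-numbered probes with and without it correlated at 0.64 and 0.55 on nucleus replicates 2 and 3, and at 0.46, 0.13 and 0.23 on cytoplasm replicates 1, 2 and 3. Few late-numbered probes were well above background on the cytoplasm arrays, so that this does not decide it. Slide and group cannot be told apart, with 0 slides holding both groups, and a difference between the fractions in the RNA itself stays open as untested.

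With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The split by fraction called 8 probes and the highest other split 8942, so that 2 splits gave as many. That other split set nucleus replicates 1 and 2 with cytoplasm replicate 2 against the rest, which after the dye term compares nucleus replicate 1 with the other Cy3 samples and points to the structure given by that array. For the gap between late-numbered and other probes, 2 splits gave a value as large, 1.41 for the real one and 2.1 for the highest other. For the suffix classes 5 splits did, with -0.44 for the real one and a size of 1.04 for the highest other.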

How the results depend on the processing

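Settings of the 5-array counts, the central part of the array, cytoplasm replicate 2 read from the other file, the table without normalization between arrays, the filters on 5 arrays, the class tests on probes above background on all arrays and the numbers of brightest probes were chosen after seeing the data. Signal over background is a limit, with 8037 probes well above it on the dimmest cytoplasm array and 103550 on the brightest nucleus array. The cause of the changes was not tested unless it is given.

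On 6 arrays, against 8 higher and 0 lower, all settings moved the count of higher probes by over 1.5 times. No background correction, 75th percentile scaling, the series table with quantile normalization, no filter, a filter on all 6 channels, slide as a random block and no trend gave 0 and 0 in limma, with 76 to 7018 higher and 1080 to 7282 lower at the unadjusted threshold. An offset of 16 gave 34 and 3, no dye term 34 and 4, loess with Aquantile 159 and 11, the processed intensity 2212 and 23, and the table as deposited 2989 and 106. Scan day with dye as blocks gave 7108 and 12485, the central part of the array 1 and 0 among 4467 probes, and cytoplasm replicate 2 from the other file with replicate 3 left out 46 and 0. Leaving out 1 sample gave 0 to 5169 higher and 0 to 2941 lower.

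With the replicate number as a block, 1401 were higher and 233 lower on 6 arrays, and 6842 and 3924 on 5. Same-numbered samples deviated from their group means with correlations of -0.0032, -0.080 and 0.15 across probes, and not every sample correlated best with its own number, so the numbers were not taken as pairs. Same-numbered samples do share dye and array position, and replicate 1 of both groups a scan day. The block changed no call of the probe classes on 6 arrays. On 5 arrays it made the suffix gap -0.18 (camera, adjusted p = 0.019).

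On 5 arrays, 13 of 20 settings kept the higher count and 14 of 20 the lower count within 1.5 times of 5169 and 2941. The others were 75th percentile scaling with 15459 higher, the table as deposited with 16550 higher and 14415 lower, no trend with 1917 lower, cytoplasm replicate 2 from the other file with replicate 3 left out with 1560 lower, and the filters on at least 3 of 5 and on all 5 channels with 1403 and 592 higher, from fewer probes tested. Leaving out a further sample gave 1907 to 7325 higher and 927 to 3966 lower; where 1 nuclear sample was left, it was assumed to vary like the others.

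The gap of late-numbered probes kept its direction in all 15 settings, from 0.0506 to 2.09, and its call in 14, the exception being probes above background on all 5 arrays (0.0506). Leaving out 1 sample gave 0.56 to 2.09. For the suffix classes, 3 settings reversed the gap of -0.44: 75th percentile scaling (0.34), probes above background on all 6 arrays (0.59) and on all 5 (0.97). The call was lost with an estimated correlation (-0.44), with no filter (-0.0452), and without nucleus replicate 1 with an estimated correlation (-0.0279), and leaving out 1 sample gave -0.728 to -0.0279. Differences in the share of late-numbered probes among the brightest stayed positive in all 10 settings, at 18.0 to 33.0 points, as did those in the share above background in all 7, at 38.1 to 49.9. Their exact tests cannot pass 0.05. The 4 named probes kept their direction in every setting that tested them, but Catma_IRHS_34483 lost its call in 9 of 20 and Catma_IRHS_49555_r in 8 of 20. Their log2 differences were 5.35 to 7.95 and 5.92 to 7.77, the low ends under the bounds given for the main settings. Catma_IRHS_08889 and Catma_IRHS_31441_r passed in 8 of 21 each, at -6.93 to -1.81 and -5.69 to -2.11. Not run for want of gene names were the summaries over the probes of a gene, the lists, gene structure and intronic probes. The scan day block, and the slide block with the dye term, could not be fitted on 5 arrays.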

Other observations

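The values here were looked up after the data were seen. On the 5 arrays without nucleus replicate 1, probes with neighbouring numbers had similar differences between the fractions in the late range and hardly so in the early range. Differences of late-numbered probes 1 number apart correlated at 0.63 over 2151 pairs without suffix and at 0.58 over 2245 pairs with it, and those 50 numbers apart at 0.38 and 0.34. In the early range the correlation at 1 number apart was 0.11 over 3772 pairs without suffix and 0.044 over 7660 pairs with it.

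On these 5 arrays, differences of the probe with and without the suffix correlated at 0.65 over 2918 late-numbered pairs and at 0.20 over 7600 early-numbered ones. These correlations are across probes, which are not independent replicates.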
